A study of Mactra quadrangularis with 6 samples.

How the data were processed

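The series profiled messenger RNA from the mantle, the tissue that lines and secretes the shell, of the surf clam Mactra quadrangularis (also called Mactra veneriformis). It holds 6 libraries in 2 groups, 3 labelled as acidification stress and 3 labelled as control. Each library's group and replicate number were taken from its title. The series text describes the acidified groups as kept at high pH, which is at odds with acidification. Acidified and control are therefore the names that the labels give, and what the treated water was like could not be settled. The dose and duration of the acidification, the pH reached and the meaning of the letter in the library names are not given in the sources used here. Nothing in the labels says that the libraries came from separate animals, so the p-values measure the spread among these samples, which may be technical.

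Per the labels' protocols, total RNA was extracted with Trizol, samples of high RNA integrity were kept, and poly(A) RNA was selected on oligo(dT) beads, fragmented and made into strand-marked libraries by the dUTP method. They were sequenced as paired ends on an Illumina NovaSeq instrument. Per the submitters' processing notes, the tools used were cutadapt 1.9, an adapter trimmer, HISAT2 2.2.1, an aligner, StringTie 2.1.6, a transcript assembler, and DESeq2 and edgeR. The genome build is not given in the sources used here. Positions are those of the deposited table, which places its genes on 19 chromosomes and other contigs.

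The deposited table lists 25145 genes with a position, gene ontology and pathway terms, and the description of the best match in another species. Of these, 13856 had an informative description, meaning one that was not uncharacterized, hypothetical or unnamed. For each library it holds a raw count per gene, deposited by the authors as whole numbers, and an FPKM value deposited by the authors, which scales counts by library size and transcript length, per the file headers. A further 12 columns belong to 6 libraries outside the listed samples and were not used here. Gene names in the text are the descriptions in the table, so a name gives the closest described relative and not a tested function. Total counts per library ran from 28482358 to 37066703. At this depth counting error is small for genes with ample counts, and the spread between libraries sets the precision.

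The design fixed before the data were examined assumed FPKM values and stated that counts, if present, would be tested instead. Because the table held counts, edgeR 4.0.16 (R 4.3.3) was run on the counts as deposited, with its filterByExpr filter, TMM scaling between libraries, a quasi-likelihood fit of group alone (glmQLFit, glmQLFTest) and Benjamini-Hochberg adjustment. A gene counted as changed at an adjusted p under 0.05, and a further count required a change of at least 2-fold. The filter left 17790 genes and set 7355 aside. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. FPKM means are given with the SD over 3 libraries. Where all control libraries held no count, the fold is a lower bound against a floor of 3 counts per library.

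Gene lists were also fixed before the data were examined, as text patterns on the descriptions: 16 for processes related to the treatment and 6 for markers of other cells that a piece of mantle may hold. Lists were tested with limma 3.58.1, using camera at a preset correlation between genes of 0.01 on log2 CPM (counts scaled to library size) with a prior count of 2. Camera asks whether a list shifted relative to all other genes. Each call was repeated with a correlation estimated from the libraries, and with fry, which asks whether the genes of a list move on balance in one direction. Adjustment was over the 22 lists. Several patterns matched words they were not meant for (the germ line pattern matched binding and lysine, for example), and a narrowed version was added after the descriptions were seen. Annotation terms with 10 to 300 tested members were tested by camera in the same way. A transcript length for each gene was recovered from the ratio of its count to its FPKM, which fixes the length up to one constant.

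Named genes followed a rule fixed in the same way. It took the 10 genes per direction with the largest change among those past the test with an informative description. Because no gene passed, it took instead the 10 per direction with the smallest unadjusted p, counting a description once, and these are given as values and not as changed. From each list it took the 2 members with the smallest p in each direction, and 4 for calcification and for acid-base transport.

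The procedure was tested on simulated counts drawn from the means, sizes and spread of the 6 libraries over 17790 genes, with 50 genes changed at each size. The spread was as estimated by edgeR, with no trend over transcript length and no outlying library. The rates below may therefore not hold for the real libraries. For the comparison of 3 acidified with 3 control libraries, edgeR called 2% of the genes changed 2-fold, 56% of those changed 4-fold, 64% of those changed 8-fold and 80% of those changed 16-fold, along with 10 unchanged genes. DESeq2 called 80% of the genes changed 4-fold, along with 96 unchanged genes. With no change simulated, edgeR called 0 genes. The cytosolic ribosome list, shifted by a log2 fold change of 0.8 in the simulation, was called, and 0 of 40 unshifted random lists were. Smaller list shifts were not simulated, so the power to find them is not known. Because the genes were drawn independently, the simulation could not show false list calls from genes that move together.

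Alternatives fixed beforehand were limma on log2(FPKM + pseudocount) with other pseudocounts, filters, scalings and weights, DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, the replicate number as a further term, each library left out in turn, and the other list tests. Added after the data were seen were library size scaling alone, robust edgeR, limma-voom, limma-trend at a pseudocount of 1, removal of the trend with transcript length, the narrowed lists, and library omission and scaling for the terms. Their effects are given in the closing section.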

Results

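The data are 6 mantle transcriptomes of the surf clam Mactra quadrangularis, 3 from an ocean acidification treatment and 3 from controls. The series title names shell colour, oxygen consumption and ammonia excretion as the study's wider subject. The libraries held 28482358, 30380052 and 37066703 counts in the acidified group and 32512165, 32992500 and 31929388 in the control group. The single comparison asks which mantle transcripts differ between acidified and control seawater.

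Genes of the cytosolic ribosome were higher together in the acidified libraries, with a median log2 fold change of 0.81 over 74 genes, and 71 of them lay above 0 (camera, adjusted p = 7.42e-35, and adjusted p = 0.271 with an estimated correlation). Genes of oxidative phosphorylation had a median of 0.51 over 59 genes and antioxidant genes a median of 0.39 over 82, with adjusted p = 0.613 and adjusted p = 0.298 with an estimated correlation. Over all genes, short transcripts were higher and long ones lower, with medians from 0.29 in the shortest 10% to -0.36 in the longest 10%. Of single genes, 2 sialic acid-binding lectins and an interferon-induced protein 44-like gene were among the 10 with the smallest p on the higher side, and a mucin-2-like gene and glutamine synthetase among the 10 on the lower side. No single gene passed the edgeR test over all genes.

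Of 17790 genes tested, 0 had an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.118, shared by 167 genes. At an unadjusted p under 0.05 there were 3099 genes, 1652 higher and 1447 lower, where 890 would arise by chance. Of these, 634 higher and 686 lower differed at least 2-fold. DESeq2 called 1113 genes on the same counts, 654 higher and 459 lower, of which 373 and 332 differed at least 2-fold. The 2 groups did not overlap for 25.6% of genes, where chance gives 10%. With library size as the only scaling, 15.5% of the genes at an unadjusted p under 0.05 were higher, against 53.3% with TMM scaling, and the median log2 fold change of all genes was -0.33. On FPKM rescaled to an equal sum the share was 6.83% and the median -0.39. Fold changes below use TMM scaling, so they are relative to the bulk of genes. FPKM values are as deposited, without TMM scaling. The ratio of acidified to control mean FPKM therefore tends to lie below the fold change given beside it.

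Among the genes higher in the acidified libraries, the smallest p belonged to the sialic acid binding lectin Mve06G016030 (chromosome 6, 50654863 to 50656426), one of a family of secreted sugar-binding proteins. Its FPKM was 82.4 ± 24.7 (SD, n = 3) in the acidified group and 20.3 ± 5.27 (SD, n = 3) in the control group, a log2 fold change of 2.36 ± 0.25 (SE). A second lectin, Mve19G007270 (chromosome 19, 27066235 to 27067762), had 25.8 ± 3.96 against 5.33 ± 1.25 FPKM, a log2 fold change of 2.61 ± 0.30. Many genes carry this description, so reads may be shared among them, and the separate values are uncertain. The cdc42 homolog Mve02G009270, a small GTPase of cell polarity, had a log2 fold change of 1.20 ± 0.16. The RNA-binding protein PNO1 gene Mve02G011010, whose product helps assemble the small ribosomal subunit, stood at 257 ± 50.3 against 146 ± 11.6 FPKM. A SVEP1-like gene (Mve14G009310, a secreted adhesion protein) differed by 1.87 ± 0.26, and a mitochondrial lipid-transfer protein of the PRELI family (Mve13G003810) by 1.14 ± 0.18. A CUB and LDL domain trypsin-like peptidase (Mve11G006080) differed by 1.09 ± 0.17.

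The interferon-induced protein 44-like gene Mve04G004480 had no count in any control library and 5.22 ± 3.43 FPKM in the acidified group, at least 47.2-fold higher. The HORMA domain-containing protein 1-like gene Mve12G011140, a relative of a protein of meiotic chromosomes, also had no count in the controls, and at 0.94 ± 0.10 FPKM it was at least 25.0-fold higher. The adjusted p was 0.118 for each of these 20 named genes, 10 per direction, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In DESeq2 their adjusted p ran from 2.93e-14 to 0.000138. DESeq2 used the same counts by which the genes were chosen, so these values are no independent test.

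Among the genes lower in the acidified libraries, the mucin-2-like gene Mve09G004150 (chromosome 9, 13244572 to 13285117), a relative of gel-forming mucus proteins, stood at 6.84 ± 1.92 FPKM in the acidified group and 47.6 ± 23.0 in the control group, a log2 fold change of -2.45 ± 0.33. Glutamine synthetase Mve14G000320, which fixes ammonia into glutamine, stood at 337 ± 30.5 FPKM in the acidified group and 846 ± 104 in the control group, a log2 fold change of -0.99 ± 0.17. The choline transporter-like protein 4 gene Mve14G013890 differed by -2.31 ± 0.37, the ADAMTS18-like protease gene Mve06G013150 by -2.22 ± 0.35 and the heparan sulfate 3-O-sulfotransferase 6-like gene Mve09G013850 by -2.11 ± 0.30. The GRAM domain 1B-like gene Mve10G002410, a relative of a sterol transporter, differed by -1.71 ± 0.28, and the galactocerebrosidase-like gene Mve13G000900, a relative of a lysosomal glycolipid hydrolase, by -1.68 ± 0.26. The neuroglian-like adhesion gene Mve18G008330, the myosin-IIIa-like gene Mve10G008630 and the STEAP2-like metal reductase gene Mve15G000830 differed by -1.38 ± 0.22, -1.35 ± 0.21 and -1.02 ± 0.17. In each of the 20 named genes the 3 acidified libraries lay on one side of the 3 control libraries. The genes were chosen by small p in these same libraries, which favours such separation.

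**Figure D1:**
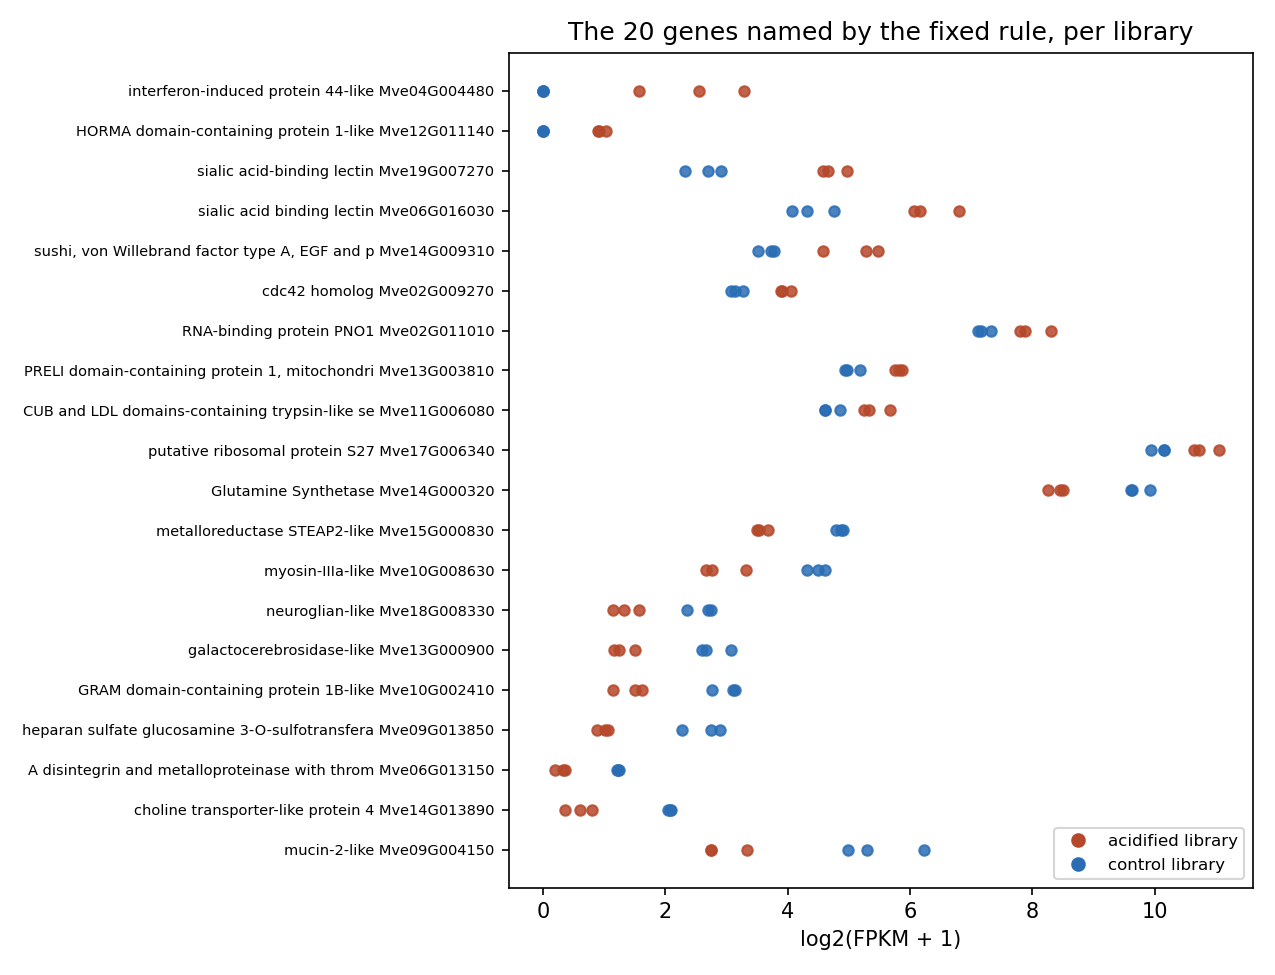
Each point is one library's log2(FPKM + 1) for the 20 genes named by the fixed rule, red for acidified and blue for control. The groups are separate in every gene shown, which the choice of genes by small p favours. The controls of the interferon-induced protein 44-like and HORMA domain genes lie at 0.

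Cytosolic ribosomal protein genes were higher than other genes (camera, adjusted p = 7.42e-35), and the adjusted p = 0.271 with an estimated correlation. Of the 74 members, 66 were higher and 0 lower when adjusted over the list alone, and 0 passed over all genes. Ribosomal protein S27 (Mve17G006340) stood at 1798 ± 275 FPKM in the acidified group and 1084 ± 87.3 in the control group. Ribosomal protein S14 (Mve01G001660) stood at 2974 ± 122 against 2001 ± 29.4. The members below 0 with the smallest p were S6 kinases, Mve05G013790 at -0.83 ± 0.54 and Mve02G007020 at -1.06 ± 0.78, which are signalling enzymes and not part of the ribosome. DESeq2 called 60 of the list's genes. Fry gave an adjusted p of 0.0146. After quantile normalization of the FPKM values the list's median was 0.16, still above 0. Ribosomal protein transcripts are short, and 10000 random lists matched on transcript length and expression had a median of 0.45 and a 95% range of 0.31 to 0.59, below the list's median.

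Oxidative phosphorylation genes were also higher than other genes (camera, adjusted p = 3.34e-12), and the adjusted p = 0.613 with an estimated correlation. Of the 59 members, 30 were higher and 0 lower at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. A subunit of complex I, NDUFB11 (Mve08G006970), stood at 163 ± 7.66 against 117 ± 5.85 FPKM. A complex I assembly factor (Mve16G000460) differed by 1.01 ± 0.22. The cytochrome c oxidase assembly factor 4 homolog Mve07G013400 and a probable NADH dehydrogenase Mve11G010380 lay lower, at -1.17 ± 0.72 and -0.31 ± 0.21. The call was lost with quantile normalization (adjusted p = 0.0617), where the median relative to all genes was 0.13, and in fry (adjusted p = 0.136), within a range of 9.58e-14 to 0.613 over all alternatives. Random lists matched on transcript length and expression had a median of 0.43 and a 95% range of 0.26 to 0.59, which held the list's median.

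Antioxidant genes had an adjusted p of 0.0017 in camera, and the adjusted p = 0.298 with an estimated correlation. Of the 82 members, 17 were higher and 3 lower at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. Glutathione S-transferase A (Mve02G015270), which conjugates glutathione to toxic compounds, stood at 37.7 ± 9.89 against 13.9 ± 5.13 FPKM. A DHAR2-like glutathione S-transferase (Mve03G019250) differed by 1.14 ± 0.26. A thioredoxin-related transmembrane protein 1 (Mve02G005210) and thioredoxin domain-containing protein 9 (Mve09G009240) lay at -1.15 ± 0.37 and -0.51 ± 0.17. On the list's mean the acidified libraries lay at 0.10, 0.50 and 0.52 and the highest control at 0.06. Random lists matched on transcript length and expression had a median of 0.21 and a 95% range of 0.06 to 0.36, below the list's median. The call was lost with the trend over length removed (adjusted p = 0.0529), where the median relative to all genes was 0.31 against 0.39 before, with quantile normalization (0.111), at a mean FPKM of at least 5 (0.120) and in fry (0.0967), within a range of 0.000133 to 0.298 over all alternatives.

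Genes of calcification had a median log2 fold change of 0.14 over 58 members (camera, adjusted p = 0.0270), and the adjusted p = 0.271 with an estimated correlation. Of these, 11 were higher and 1 lower at an unadjusted p under 0.05, and 2 were higher when adjusted over the list alone. Those 2 were perlucin-like Mve03G005040, a relative of a shell matrix lectin, with a log2 fold change of 1.10 ± 0.21, and the GPI-anchored carbonic anhydrase Mve11G007100, which interconverts carbon dioxide and bicarbonate, at 4.76 ± 0.716 against 1.92 ± 0.414 FPKM. A tyrosinase-like gene (Mve06G002370) and chitinase-3-like 1 (Mve16G007370) differed by 1.89 ± 0.49 and 2.07 ± 0.55. The lower members with the smallest p were 2 calcium pumps that the pattern for carbonic anhydrases matched by accident, Mve11G009160 at -0.51 ± 0.19 and Mve08G014370 at -0.80 ± 0.34. That accident of wording does not mean that the pumps have no part in calcification. The narrowed list of 55 members, which leaves such matches out, had a smaller adjusted p of 0.0129 in camera. Next to the pumps came a tyrosinase (Mve11G003950, -0.81 ± 0.43) and a BMP receptor (Mve01G007620, -0.58 ± 0.45). The call was lost without control replicate 3 (adjusted p = 0.0749) in edgeR without a filter on low counts (0.170), in fry (0.0945) and in each alternative fitted to FPKM values but that with rescaling to an equal sum, within a range of 0.0109 to 0.328. The median relative to all genes was 0.21 without acidified replicate 2, 0.24 without acidified replicate 3 and 0.23 without control replicate 2. With the replicate number as a block it was 0.25. With the trend over transcript length removed it was 0.09, and the call stayed (camera, adjusted p = 0.0463). Random lists matched on transcript length and expression had a median of 0.10 and a 95% range of -0.07 to 0.26, which held the list's median.

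Genes of innate immunity had a median of 0.30 over 221 members (camera, adjusted p = 0.0270), and the adjusted p = 0.271 with an estimated correlation. Of these, 27 were higher and 11 lower at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. The median was the same with the interferon-induced protein 44-like gene held at its lower bound. This follows from using a median, since both values of that gene lie above it. A macrophage mannose receptor 1-like gene (Mve14G002310) stood at 4.70 ± 1.56 against 1.17 ± 0.297 FPKM, while 2 genes of C1q-domain proteins, Mve02G010330 and Mve02G010370, lay at -1.60 ± 0.42 and -1.38 ± 0.40. The call was lost without acidified replicate 1 (adjusted p = 0.0862), acidified replicate 3 (0.186), control replicate 1 (0.0667) or control replicate 2 (0.125), with the trend over transcript length removed (0.198), in edgeR without a filter on low counts (0.414), in fry (0.0945) and in 4 of the alternatives fitted to FPKM values, within a range of 0.00299 to 0.414. The median relative to all genes was 0.17 without acidified replicate 3 and 0.17 with the length trend removed, against 0.30 before. Random lists matched on transcript length and expression had a median of 0.10 and a 95% range up to 0.20, below the list's median.

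Cell cycle genes were lower than other genes, with a median of -0.29 over 56 members (camera, adjusted p = 0.0155), and the adjusted p = 0.614 with an estimated correlation. Of these, 10 were lower and 3 higher at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. The catalytic subunit of DNA polymerase epsilon (Mve07G009710) differed by -1.09 ± 0.25 and DNA topoisomerase 2-binding protein 1 (Mve07G000030) by -0.71 ± 0.20. A CDC5-like gene (Mve05G008530), whose relatives act in splicing, and a CDC123 homolog (Mve11G007710), whose relatives act in translation initiation, lay at 1.57 ± 0.45 and 0.79 ± 0.28. The call was lost without acidified replicate 1 (adjusted p = 0.228) or control replicate 1 (0.0559), with the trend over transcript length removed (0.0805), with quantile normalization (0.0541), at a mean FPKM of at least 5 (0.120) and in fry (0.170), within a range of 0.000744 to 0.614. On the list's mean the acidified libraries lay at -0.56, -0.33 and -0.07 and the controls at 0.01, 0.05 and -0.06, so acidified replicate 3 was near control replicate 3. Random lists matched on length and expression had a median of -0.06 and a 95% range of -0.24 to 0.12, above the list's median.

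Of the markers of other cells, the digestive gland list was higher, with a median of 0.32 over 32 members (camera, adjusted p = 0.00233), and the adjusted p = 0.271 with an estimated correlation. Of these, 6 were higher and 0 lower at an unadjusted p under 0.05, and 1, the trypsin-like peptidase Mve11G006080, was higher when adjusted over the list alone. A probable maltase (Mve07G010080) stood at 36.8 ± 1.21 against 29.6 ± 0.839 FPKM. Inter-alpha-trypsin inhibitors, which are plasma-type proteins matched by accident, lay at -0.24 ± 0.19 (Mve08G008930) and -0.30 ± 0.32 (Mve13G007190). On the list's mean the groups overlapped, with acidified libraries at 0.28, 0.25 and 0.61 and control libraries at -0.41, 0.29 and 0.12. Without control replicate 1, the lowest, the median relative to all genes was 0.17 and the call was lost (adjusted p = 0.0718). It was also lost with quantile normalization (0.0889), at a mean FPKM of at least 5 (0.168) and in fry (0.0945), within a range of 0.00111 to 0.271 over all alternatives. Random lists matched on transcript length and expression had a median of 0.15 and a 95% range of -0.10 to 0.36, which held the list's median.

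**Figure D2:**
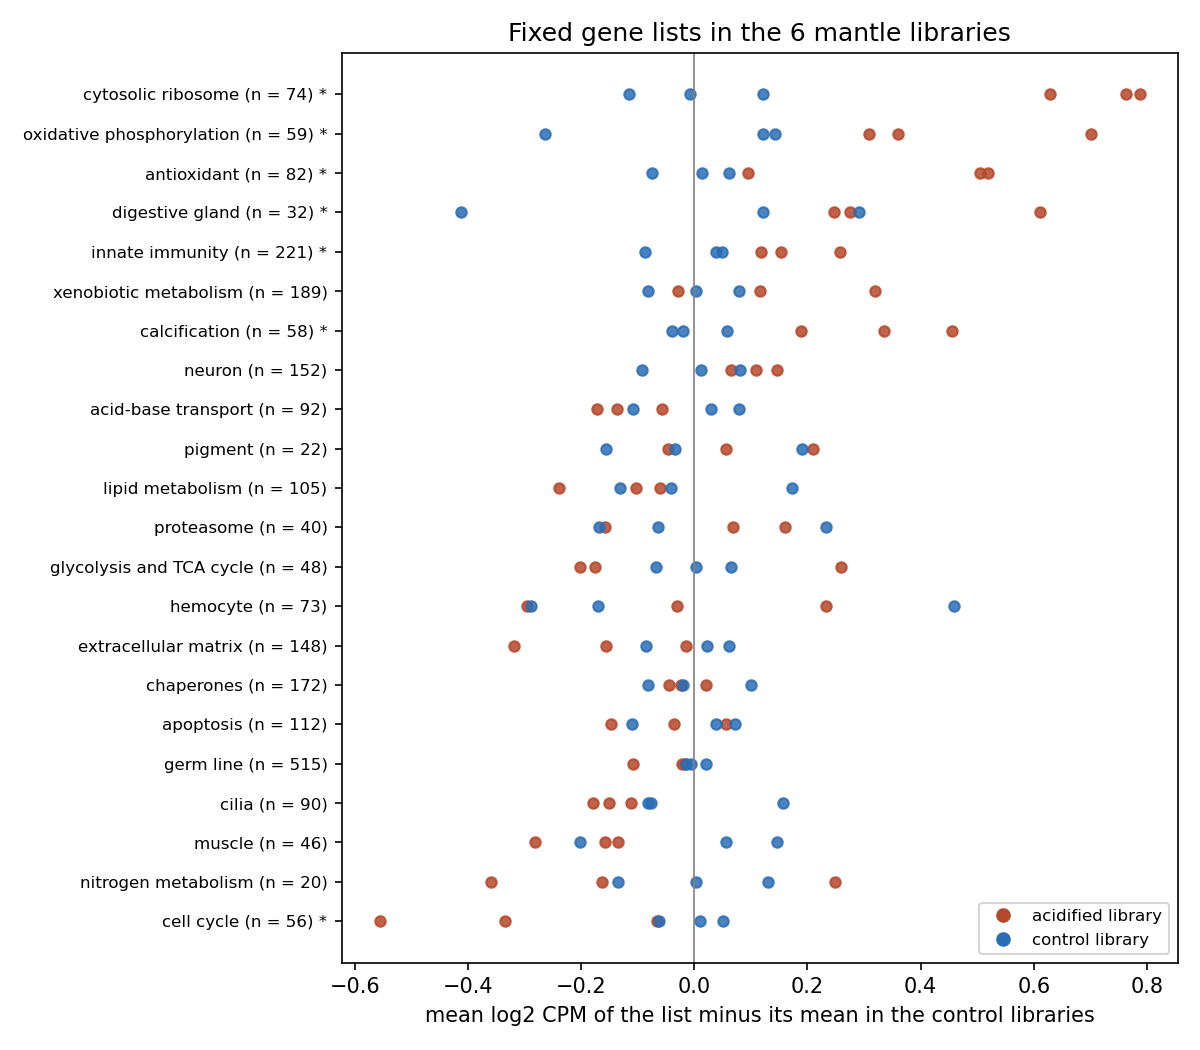
Each point is one library's mean log2 CPM over the tested members of a fixed list, minus the mean of the 3 control libraries. Lists with an asterisk had an adjusted p under 0.05 in camera at the preset correlation. The 3 acidified libraries lie between 0.63 and 0.79 for the cytosolic ribosome, above the highest control at 0.12.

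The acid-base transport list showed no shift as a group (camera, adjusted p = 0.887 over 92 members), with 5 members higher and 10 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. An electroneutral sodium bicarbonate exchanger (Mve19G005060) differed by 0.74 ± 0.17, and subunit e of the V-type proton pump (Mve13G006420) stood at 116 ± 8.80 against 87.8 ± 12.6 FPKM. A sodium-driven chloride bicarbonate exchanger (Mve19G001690) lay at 1.73 ± 0.495 against 4.57 ± 0.502 FPKM, a sodium/hydrogen exchanger 3-like gene (Mve06G008550) differed by -0.96 ± 0.26 and subunit a of the proton pump (Mve07G002930) by -0.94 ± 0.29. Monocarboxylate transporters made up most of the list, and without them 36 members had a median of -0.22 (camera, adjusted p = 0.241). They included 2 of the higher genes (Mve02G006390, 1.89 ± 0.59, and Mve15G008760, 0.94 ± 0.36) and a sodium-coupled member among the lower (Mve15G008810, -0.86 ± 0.20).

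The nitrogen metabolism list, which relates to ammonia handling, had a median of -0.29 over 20 members and was not called (camera, adjusted p = 0.142). The median relative to all genes was -0.14 without acidified replicate 1 and -0.15 without acidified replicate 3, and on the list's mean acidified replicate 2 lay at 0.25, above the highest control at 0.13. On FPKM without a filter the list was called lower (adjusted p = 0.0413). Of these, 3 were lower when adjusted over the list alone: glutamine synthetase (Mve14G000320), AMP deaminase 2 (Mve07G013590, -1.49 ± 0.36) and ammonium transporter 1 (Mve16G004240, -0.75 ± 0.20), the last named after its values were seen. Ornithine decarboxylase antizyme 1-like (Mve17G007820) and an Rh type A-like ammonium transporter (Mve14G010620) lay at 0.55 ± 0.19 and 1.13 ± 0.61. The transporter's rise came from acidified replicate 2 alone. Its FPKM was 3.56, 14.4 and 2.85 in the acidified libraries and 4.17, 3.05 and 5.02 in the controls.

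Chaperone genes as a list were not called (camera, adjusted p = 0.887 over 172 members), although heat shock protein 22 (Mve04G009850), a small chaperone, was higher when adjusted over the list alone, at 25.6 ± 10.3 against 6.38 ± 2.05 FPKM. An HSP70 12A-like gene (Mve14G010460) differed by 1.37 ± 0.32, and the co-chaperones DNAJC7-like (Mve19G005020) and DNAJA2-like (Mve06G000280) by -1.33 ± 0.25 and -0.84 ± 0.22. Lipid metabolism genes were not called (camera, adjusted p = 0.920 over 105 members), with 1 higher and 1 lower adjusted over the list alone. Those were an adipocyte-like fatty acid-binding protein (Mve11G007610) at 170 ± 42.3 against 103 ± 7.72 FPKM and fatty acid synthase (Mve01G012410) at 8.33 ± 2.06 against 45.2 ± 21.7. A pancreatic lipase-related gene (Mve03G016740) differed by 0.91 ± 0.25 and acetyl-CoA carboxylase-like (Mve05G013740), the enzyme before fatty acid synthase, by -1.02 ± 0.26. The carboxylase and fatty acid synthase genes are both among the longest 10% of transcripts, where the median of all genes was -0.36.

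Xenobiotic metabolism genes were not called (camera, adjusted p = 0.520 over 189 members), with 2 higher and 2 lower adjusted over the list alone. The higher were sulfotransferase 1 family member D1-like (Mve10G000410), at 15.9 ± 13.0 against 0.883 ± 0.266 FPKM, and carbohydrate sulfotransferase 3-like (Mve16G013060), at 2.22 ± 0.204 against 0.554 ± 0.144. The lower were the heparan sulfate sulfotransferase 6-like gene and galactose-3-O-sulfotransferase 3 (Mve15G008380, -1.94 ± 0.37), so 3 of these 4 belong to sugar sulfation and not to detoxification. Apoptosis genes were not called (adjusted p = 0.846 over 112 members), with a tumor necrosis factor gene (Mve15G006060) at 69.4 ± 23.8 against 21.3 ± 11.7 FPKM, a C1q and TNF-related gene (Mve05G007300) at 2.65 ± 0.75, and a TNF receptor (Mve04G015130) and a death domain gene (Mve15G000960) at -1.13 ± 0.27 and -1.31 ± 0.31. The C1q and TNF-related gene rose mostly in acidified replicate 2. It had 50.7, 432 and 105 FPKM in the acidified libraries and 46.7, 29.2 and 45.5 in the controls.

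Glycolysis and TCA cycle genes were not called (adjusted p = 0.855 over 48 members). They were called lower without acidified replicate 3 (adjusted p = 0.0453), on FPKM without a filter (0.0244) and at a mean FPKM of at least 5 (0.0382), within a range up to 0.993 over all alternatives. The members with the smallest p in each direction were ATP-citrate synthase (Mve12G006360) at -0.93 ± 0.27, phosphofructokinase (Mve18G003940) at -0.73 ± 0.24, malate dehydrogenase (Mve11G006600) at 0.55 ± 0.29 and ketohexokinase-like (Mve11G008630) at 0.79 ± 0.43. The proteasome list was not called (adjusted p = 0.887 over 40 members), with subunit beta type-6 (Mve04G014160) and regulatory subunit 10B (Mve02G005880) at 1.14 ± 0.42 and 0.44 ± 0.16, and ECM29 (Mve03G006920) and regulatory subunit 3 (Mve07G010810) at -0.57 ± 0.23 and -0.31 ± 0.17. Extracellular matrix genes were not called (adjusted p = 0.745 over 148 members), with integrin alpha-3-like (Mve12G008680) at 1.19 ± 0.24, fibrillin-3 (Mve12G008190) at 1.17 ± 0.25 and a matrix metalloproteinase (Mve11G013960) at -1.60 ± 0.41, while the ADAMTS18-like gene passed adjusted over the list alone.

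Pigment genes, which bear on shell colour, were not called (adjusted p = 0.920 over 22 members). The copper oxidase laccase-2-like (Mve06G011390) stood at 30.7 ± 3.19 against 67.4 ± 13.2 FPKM and the heme synthesis gene 5-aminolevulinate synthase (Mve08G010130) at 7.70 ± 0.144 against 16.1 ± 4.86, while biliverdin reductase A-like (Mve10G010810) differed by 0.54 ± 0.22. None of the 22 passed adjusted over the list alone.

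The other lists of cell type markers were not called: muscle (adjusted p = 0.142 over 46 members), cilia (0.520 over 90), neuron (0.745 over 152), germ line (0.745 over 515) and hemocyte (0.960 over 73). The muscle list was called lower without control replicate 3 (adjusted p = 0.00588), with library size as the only scaling (0.0290) and in 5 of the alternatives fitted to FPKM values, within a range of 0.00306 to 0.941. The cilia list was called lower with library size as the only scaling (0.0290) and on FPKM without a filter (0.0110). In muscle, a non-muscle myosin heavy chain (Mve01G017770) and filamin-C (Mve15G004200) lay at -0.74 ± 0.16 and -0.80 ± 0.19, and a myosin regulatory light chain (Mve18G008220) and a titin-like gene (Mve19G000480) at 0.67 ± 0.18 and 0.49 ± 0.21. In cilia, intraflagellar transport 43 (Mve02G009850) and an axonemal dynein light chain (Mve01G002760) lay at 0.81 ± 0.18 and 0.86 ± 0.22, and sperm-associated antigen 1-like (Mve12G001990) and intraflagellar transport 122 (Mve08G008230) at -1.35 ± 0.29 and -0.77 ± 0.20. In neuron, tryptophan 5-hydroxylase 1-like (Mve05G008200), the first enzyme of serotonin synthesis, lay at 1.52 ± 0.29 and an acetylcholine receptor subunit (Mve09G004470) at 2.54 ± 0.49, against synaptotagmin 1 (Mve05G011100) at -0.84 ± 0.18 and a kainate receptor (Mve05G012620) at -1.16 ± 0.31.

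In hemocyte, 4 members were higher and 2 lower adjusted over the list alone. The higher were the SVEP1-like gene, the mannose receptor and, named after their values were seen, a second gene of each kind (Mve14G009320, 2.07 ± 0.38, and Mve14G001690, 1.35 ± 0.32). The lower were a von Willebrand domain 5A-like gene (Mve09G012070) and another SVEP1-like gene (Mve15G008070), at -1.17 ± 0.25 and -1.48 ± 0.36. The SVEP1-like and von Willebrand domain genes entered through the words von Willebrand, counted as accidental matches, and are not taken as hemocyte markers. Narrowed without such matches, the hemocyte list kept 23 members with a median of 0.12 and was not called (camera, adjusted p = 0.633). The germ line list had 5 members higher adjusted over the list alone, each an accidental match: 3 sialic acid-binding lectins, PNO1 and, named after its values were seen, a METTL21A lysine methyltransferase (Mve19G003250, 1.09 ± 0.17). Other members were an RNA-binding protein 4.1-like gene (Mve02G000770) and a CHD4-like helicase (Mve04G005430), at -1.22 ± 0.23 and -0.85 ± 0.18. Narrowed to the intended words, the germ line list kept 37 members and was not called (adjusted p = 0.951). The median, mean and test of a list differed in sign for acid-base transport, chaperones, apoptosis, hemocyte, lipid metabolism and the proteasome, none of which was called.

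Among 1514 annotation terms, 42 were higher and 75 lower in camera, and with an estimated correlation 0 were called (smallest adjusted p = 0.672). Without acidified replicate 3 the total of 117 became 68. The higher terms were led by the KEGG ribosome pathway (126 genes, median 0.72), the cytosolic large and small ribosomal subunits (53 and 35 genes, medians 0.80 and 0.81), structural constituent of ribosome (157 genes, 0.65) and cytoplasmic translation (27 genes, 0.81). They also included KEGG oxidative phosphorylation (87 genes, 0.44), respiratory chain complex I (23 genes, 0.59) and translation (147 genes, 0.42). The lower terms were led by serine/threonine kinase activity (161 genes, -0.36), microtubule motor activity (60 genes, -0.47), protein phosphorylation (185 genes, -0.35) and ruffle (20 genes, -0.63). Protein kinase activity (102 genes, -0.42), the kinesin complex (39 genes, -0.66), tight junction assembly (10 genes, -0.68) and GTPase activator activity (104 genes, -0.37) followed.

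Fold change followed transcript length across all genes. The median log2 fold change went from 0.29 in the shortest 10% of genes to -0.36 in the longest 10%. Several lower genes named above are in the longest 10%: fatty acid synthase, acetyl-CoA carboxylase-like, DNA polymerase epsilon and the calcium pump Mve11G009160. The titin-like gene, also among the longest, was higher. How much of the difference of single genes follows the trend was not tested. The difference between the longest and shortest 10% was -0.47, -0.63 and -0.82 in the acidified libraries, and -0.18, -0.02 and 0.17 in the control libraries, each control being set against the other controls. With this trend removed, 4 lists were called, all of them higher, and 25 terms, 21 higher and 4 lower.

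**Figure D3:**
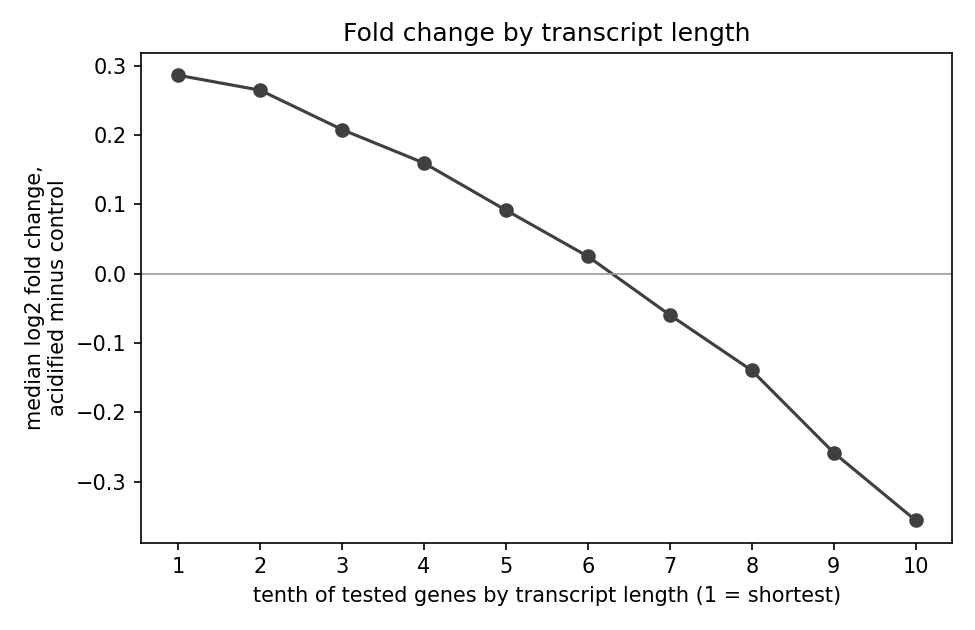
Points give the median log2 fold change, acidified minus control, in 10 equal groups of the tested genes ordered by transcript length, with 1779 genes in each. The median goes from 0.29 in the shortest group to -0.36 in the longest.

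The control libraries resembled each other more closely than the acidified ones. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.917 to 0.927 within the controls, 0.894 to 0.904 within the acidified group and 0.878 to 0.908 between groups. The first principal component held 31.5% of the variance. On it the controls lay at 47.9 to 51.5 and the acidified libraries at -2.04, -34.5 and -113. Acidified replicate 3 lay farthest from the rest. On the second component, with 20.5% of the variance, acidified replicate 2 lay at 99.5 and the other libraries between -53.5 and 6.08. Acidified replicate 1 correlated with control replicates 1 and 2 at 0.907 and 0.908, and with its own group at 0.904 and 0.894. Without acidified replicate 3 the number of genes at an unadjusted p under 0.05 was 2577, and 0 passed the adjusted test. Without acidified replicate 1, by contrast, 2 genes passed, both higher and neither with an informative description (Mve13G000560 and Mve18G005170).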

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

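Alternatives that were added after the data were seen are library size scaling, robust edgeR, limma-voom, limma-trend at a pseudocount of 1, removal of the length trend, the narrowed lists, and omission and scaling for terms. The edgeR count of 0 changed genes became 1113 in DESeq2 (705 of them at least 2-fold) and 820 in limma on FPKM rescaled to an equal sum (661 at least 2-fold), where 779 of the 820 were lower. Leaving out one library gave 0 to 2 genes, and 0 to 2 at least 2-fold, the 2 arising without acidified replicate 1. The other gene counts were 0. The count at an unadjusted p was 1589 in FPKM with a mean of at least 5, where fewer genes were tested, and 2387 to 3182 with one library left out. Of the lists, 7 were called. With an estimated correlation 0 were, with fry 1, after quantile normalization 2, at a mean FPKM of at least 5 4, and with the length trend removed 4. The 7 were 6 higher and 1 lower, while on FPKM without a filter 10 were called, 4 higher and 6 lower, and with library size scaling alone 9, 6 higher and 3 lower. Leaving out one library gave 4 to 7, the 4 arising without control replicate 1. Of 117 terms, 0 were called with an estimated correlation, 25 with the length trend removed, 36 at a mean FPKM of at least 5 and 72 on log2(FPKM + 0.1). Leaving out one library gave 68 to 124, the 68 arising without acidified replicate 3. Apart from the fewer genes tested, the cause of these shifts was not tested. Over 26 settings the 7 called lists kept their direction and missed the threshold in 47 of 182 values, most often calcification and innate immunity. The 15 other lists flipped sign in 23 of 390 values and newly passed the threshold in 14, most often muscle and once the proteasome. The proteasome, uncalled in edgeR, turned direction and was called lower, at -0.22, on FPKM without a filter. The 20 named genes kept their direction in all settings run and passed the threshold in 34 values, from DESeq2 and from FPKM rescaled to an equal sum. Because they were chosen by small p in these same libraries, a kept direction was nearly given.

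The replicate numbers did not pair the libraries: deviations from the group means correlated at 0.0089, -0.044 and -0.0067 for equal numbers. With the replicate number as a block, 0 genes passed, 2489 had an unadjusted p under 0.05, and 7 lists and 124 terms were called. Depth, 28482358 counts or more, was not limiting for well-expressed genes, and in simulation 2% of 2-fold changes were found.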

Other observations

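The tests of the lectin family, of scaling and single libraries for the ribosome, and of the groups in this paragraph were chosen after the result was seen, as were the condition on length removal for oxidative phosphorylation and the correlation that replaced a first test of shared lectin reads. The camera p-values of these groups are unadjusted, unlike those of the fixed lists, and the 2 kinds cannot be set side by side. Unadjusted, the cytosolic ribosome had p = 0.0349 in camera with an estimated correlation. Mitochondrial ribosomal protein genes had a median log2 fold change of 0.44 over 49 members, with 15 higher and 0 lower at an unadjusted p under 0.05 (camera p = 7.33e-09, and p = 0.0425 with an estimated correlation). Their median relative to all genes stayed between 0.24 and 0.45 over 6 scalings, although on FPKM rescaled to an equal sum the median itself was -0.075, and lists matched on transcript length had a median of 0.29 and a 95% range of 0.12 to 0.46, which held the list's median. Mucin genes had a median of -0.62 over 19 members, with 7 lower and 1 higher (camera p = 0.0032, and p = 0.0621 with an estimated correlation), and stayed between -0.61 and -0.45 relative to all genes over 6 scalings. Their median of -0.62 lay below the 95% range of length-matched lists, -0.53 to 0.12. The mucin-2-like gene Mve09G004150 had the smallest p of them, and the exception upward was integumentary mucin C.1-like Mve06G000110 at 1.13 ± 0.39. Kinesin motor genes had a median of -0.61 over 31 members, with 3 lower and 0 higher (camera p = 9.41e-05, and p = 0.0294 with an estimated correlation), and stayed between -0.65 and -0.21. Their median of -0.61 lay inside the 95% range of length-matched lists, -0.62 to -0.08.

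Genes that separated the acidified libraries from each other were also seen. The undescribed gene Mve13G000560 had 1070, 23149 and 47875 counts in the acidified libraries and 918 to 1434 in the controls. The hypothetical protein gene Mve18G005170 had 0, 2725 and 3514 counts in the acidified libraries and 46 to 77 in the controls. In edgeR's leave-one-out fits both passed the adjusted test when acidified replicate 1 was left out, and not when any other library was.

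The first pattern is the trend with transcript length and the lists that follow it. The trend was present outside the range of the controls in 3 of 3 acidified libraries, which argues against one library as its source. Ribosomal protein genes lay 0.36 above the median of 10000 length- and expression-matched random lists and above all of them. Their median was at least 0.16 under the other scalings and at least 0.75 relative to all genes without any one library. These values argue against length, scaling or one library as the whole source of the shift. The matched lists drew genes singly, so they do not allow for genes that move together, and matched expression only in broad classes. With an estimated correlation the list was not called (camera, adjusted p = 0.271). A difference in RNA integrity between the groups could not be tested for these short transcripts. Cell cycle genes lay at -0.23 from their matched lists, past all but 0.49% of them, which argues against length alone, although with the trend removed their median relative to all genes went from -0.29 to -0.25 and the call ended (adjusted p = 0.0155 before and 0.0805 after), for a reason that was not tested. Oxidative phosphorylation genes lay only 0.077 above their matched lists, inside their range, and with the trend removed their median relative to all genes went from 0.51 to 0.29 and the call stayed (adjusted p = 2.95e-07), so for them length bias and an effect of acidification cannot be told apart, and a difference in RNA integrity between the groups, which would act through length, could not be tested without reads.

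The second pattern is the sialic acid-binding lectin family, 44 tested genes with a median of 1.13, 18 higher and 0 lower at an unadjusted p under 0.05 (camera p = 3.54e-10, and p = 0.00276 with an estimated correlation), of which 29 lie on chromosome 19. The family was noticed through its 2 named genes, so these camera p-values, which are also unadjusted, are not independent of that choice. Its median relative to all genes was 0.69 to 1.12 over 6 scalings. The family lay 0.94 above its length-matched lists, which argues against length bias. Reads of one gene shared among its copies remain open. Members on other chromosomes than the most abundant one had a median of 1.09, the first test, but copies on different chromosomes can share reads. The median within-group correlation with the most abundant member was 0.10 over 25 members, with a bootstrap interval, drawn over members, of -0.097 to 0.52. A candidate explanation is a rise of the family under acidification, as a hypothesis found and tested on the same data.

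The third pattern is the digestive gland list. If digestive gland tissue entered the acidified samples, its enzymes would be higher together. The 13 digestive enzymes of the list had a median of 0.43, with 11 above 0 under TMM scaling and a bootstrap interval of 0.17 to 0.65. The bootstrap drew genes and not libraries, so its interval does not measure the spread between samples. The mean FPKM, however, was higher for 7 enzymes and lower for 6, and the list's 9 cathepsin L genes had a median of 0.16. The most abundant were a probable maltase at 284 against 269 FPKM, a pancreatic lipase-related gene at 125 against 112 and a pancreatic triacylglycerol lipase-like gene at 56.0 against 63.6, and each of the 13 was also present in the control mantle. The whole list, at 0.32, lay inside the range of length-matched lists, -0.10 to 0.36, although it was still called with the trend over length removed. Control replicate 2 lay above 2 of the acidified libraries on the list's mean. Digestive tissue in the samples, the trend with length and the low control replicate 1 therefore stay open, as does a change of these genes within the mantle, which was not tested.

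The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The count of genes at an unadjusted p under 0.05 was 3099 for the real split and at most 800 for the others, so only the real split gave as many. The real split had 7 lists and 117 terms, against at most 6 and 79, and 1113 DESeq2 calls against at most 121. In each case only the real split gave as many. Each of the other splits still called 3 to 6 lists, little below the 7. Every such split has more acidified libraries on one side than on the other, so it keeps part of the group difference. Its lists are therefore no background rate, and they cannot say how many of the 7 would arise without a group difference. For the edgeR counts of 0 changed genes and 0 changed at least 2-fold, as many in each of the 10 splits is given by the 0 itself and says nothing, with 1 as the highest other for both.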
